A study of Mus musculus with 58 samples.

How the data were processed

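Single PV cells of the ventral subiculum of PV-Cre::Ai9 mice were harvested by patch pipette and made into libraries with a Nextera XT kit, per the labels' protocols. Reads were aligned with STAR to GRCm38 and edgeR was used, per the submitters' processing notes; the versions, the counting tool, the annotation, the strand setting and the role of edgeR are not given in the sources used here. The deposited count table holds whole-number counts of 25648 genes in 58 cells, not normalized. The table of normalized values that the authors deposited holds a signal, not CPM, for the 54 Pass cells: each value is the cell's count times 1 factor for all genes of that cell. Those factors, 0.866 to 1.32, follow the inverse of the TMM factors computed here with edgeR for the same cells (Pearson r = 1 across 54 cells) and leave the differences in depth in place. The deposited neurexin isoform table holds a non-negative signal of unstated unit per isoform class and per included or skipped form of each splice site. All columns of these tables matched a labelled cell, and 0 were left unmatched.

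The cells were grouped by the sex and age in their labels. The labels do not say which cell came from which of the 4 male and 3 female animals, so cells were not used as replicates. Counts of the Pass cells were summed into 4 pools (male P35, male P36, female P40 and female P42), which are independent if each animal was used at 1 age; a pool can hold several animals. The p-values therefore measure the spread between these pools only, with 2 per sex, and sex cannot be separated from age. Replicate numbers only name cells. Total counts per Pass cell were 2.05 to 52.3 M, and female cell 3 alone gave 22.8% of the counts of its pool. No pair of cells had identical counts (0 pairs), and the correlation of log2(CPM + 1) between Pass cells was 0.664 to 0.912. The 4 Fail cells were left out of the comparisons and are described by themselves.

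Genes with at least 1 count in at least 10 Pass cells that also passed edgeR's filterByExpr with sex as the group were tested, 14933 in all. The test was edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3) on pool sums with TMM normalization, two-sided, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. Standard errors are the absolute log2 fold change divided by the square root of F. Pool levels are CPM on the TMM-scaled library size, and levels per cell are CPM of the cell's own total. Gene lists with at least 3 tested members were tested with camera (limma 3.58.1) with a preset correlation of 0.01, with an estimated correlation, and with fry, adjusted over 27 lists. The lists covered neurexins and their partners, sex chromosome genes, sex steroid receptors, GABA synthesis and transport, GABA and glutamate receptors, the inhibitory postsynapse, release machinery, calcium, sodium and potassium channels, other adhesion genes, splicing regulators, nuclear oxidative phosphorylation, ribosomal proteins, mitochondrially encoded, early and stress genes, and markers of 9 cell types.

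Named genes followed a rule fixed, with the design and the lists, before the data were examined. It takes the called genes with non-overlapping pools, up to 12 per direction. Where these are under 10 it adds the 6 per direction with the smallest p and non-overlapping pools, as values and not as calls. It also takes the 2 most abundant and the 2 smallest-p members of each list and a fixed set (among them Nrxn2, Nrxn3, Nlgn2, Dag1, Pvalb, Gad1, Gad2, Slc32a1, Xist, Ddx3y, Eif2s3y, Kdm5d and Uty). Some results are not reported here, though all fits, counts of calls and lists include the genes behind them. The 99 genes reported were each run under every alternative, except that Ttll9, Ly6c1 and C1ql2 were detected in under 20 cells and have no value under that filter, and the text names those that describe a group. Male cell 5 (Sst) and the cells said to hold most counts of a gene were singled out after their values were seen, as were Egfr and Fbln1.

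For the splice sites, the share of the included form was its summed value over that of both forms, per pool; for the classes, the alpha value over the sum of the classes. A feature was compared where every pool summed to at least 100, a limit chosen after seeing the table, which kept 10 of 13 features. Pool values of splice shares and membrane measures were compared with an exact two-sided permutation test over 6 assignments, whose smallest p is 0.333, so this test cannot call a difference. Shares of cells have exact (Clopper-Pearson) 95% binomial intervals, which cover counting error only and are too narrow where amplified copies of a molecule are counted as reads, since the labels name no molecular identifiers; no interval is given for splice shares, whose unit is unknown. Coordinates are from GENCODE vM21 on GRCm38.

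The fits were tested on simulated pools with the real means, library sizes and dispersions for 14933 genes, 50 genes changed at each fold. For the female against male comparison edgeR called 12% of the genes changed 2-fold, 56% at 4-fold, 60% at 8-fold and 76% at 16-fold, and 8 unchanged genes. The adjusted threshold is easier to pass when many genes change, so these rates need not hold for the real comparison, with 2 calls. There Kdm5d and Uty, with log2 differences of -7.67 and -7.25, were not called. A simulated list of 20 genes raised 2-fold had a camera adjusted p of 6.2e-12 and 0 of 26 random lists were called. Simulated genes were drawn independently of each other, whereas the correlation estimated in the real lists reached 0.972 (mitochondrial) and 0.884 (microglial). The simulation therefore cannot show that p-values at the preset correlation hold for such lists.

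The alternatives tried were another normalization in edgeR (relative log expression, RLE), DESeq2 1.42.0, no filter on low counts, detection in at least 20 cells, cells thinned to 2054581 counts each (0 cells were shallower), limma on mean log2(CPM + 1) per pool with a pseudocount of 1, limma on log2 of the deposited normalized signal plus 1, Pass and Fail cells together, and each pool left out in turn. For splice shares they were the mean over cells and only cells with a value of at least 10 at the site, and for membrane values the median. Leaving out 7 cells of high marker levels (male cells 11, 19, 21 and 27 and female cells 16, 21 and 27) or female cell 3, the deepest, was added after seeing the data, as were fits without male cell 5 for Sst and without male cell 16 for Ly6c1. Of the 7, those chosen for Vip or oligodendrocyte marker levels were all male, and those chosen for globin or microglial levels all female. A smaller difference in these markers was therefore built into that fit. Values were computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and drawn with matplotlib 3.10.9.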

Results

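RNA was measured in single parvalbumin (PV) cells of the mouse ventral subiculum, an output region of the hippocampus. PV cells are inhibitory interneurons that release GABA, and they were marked here by a reporter (Ai9) switched on by Cre recombinase under the parvalbumin gene. The cytosol of each cell was drawn into a patch pipette, so each library is 1 cell and comes with membrane values recorded from it. The series holds 58 cells, 29 from 4 male animals and 29 from 3 female animals, and its title names Neurexin-3, sex and GABAergic inhibition as its subject. Of these, 54 carried the quality label Pass, 27 of each sex, and 4 the label Fail. The labels do not tie cells to animals, so the Pass cells were summed into 4 pools by sex and age in postnatal days (P), which share no animal if each animal was used at 1 age. The pools were male P35 (14 cells), male P36 (13), female P40 (17) and female P42 (10). Every female pool was older than every male pool, so each comparison below is of sex and age together. Total counts per Pass cell ranged from 2.05 to 52.3 M (median 11.5 M), and the pools held 173, 162, 229 and 123 M counts in the order above.

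The first question was whether the cells carried the transcripts of PV interneurons. Pvalb, which encodes the calcium buffer parvalbumin, and Gad1, Gad2 and Slc32a1, which make GABA and load it into vesicles, each had at least 1 count in 54 of 54 Pass cells (exact 95% binomial interval 93.4% to 100%). Gad1 lay above Slc17a7, the vesicular glutamate transporter of excitatory neurons, in 54 of 54 cells, Gad2 did in 50 and Pvalb in 44 (20 of 27 male and 24 of 27 female cells). Pvalb was more variable: it ranged from 1.18 to 788 CPM, with a median of 86.9, and reached 10 CPM in 47 of 54 cells (87.0%, interval 75.1% to 94.6%). Pvalb lay above Sst, the marker of somatostatin interneurons, in 40 of 54 cells (74.1%, interval 60.3% to 85.0%), 18 of 27 male and 22 of 27 female cells. Male cell 5 held 3298 CPM of Sst and 2.49 CPM of Pvalb. Slc17a7 also had a count in 54 of 54 cells and reached 10 CPM in 26 of them, so detection of a single count does not separate cell types at this depth. Markers of glia and blood were present as well, with medians over the 54 cells of 283 CPM for Mbp (an oligodendrocyte myelin gene), 53.3 CPM for C1qb (microglia) and 31.0 CPM for Hba-a1 (haemoglobin). Other oligodendrocyte markers had lower medians, 98.0 CPM for Cnp and 34.5 CPM for Mobp. For Mal, Mag, Cldn11 and Mog they were 0.673, 0.210, 0.0844 and 0.0681 CPM. The binomial intervals take each cell as an independent draw, although the cells came from 4 male and 3 female animals. The 10 CPM level was chosen after the values were seen.

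**Figure D1:**
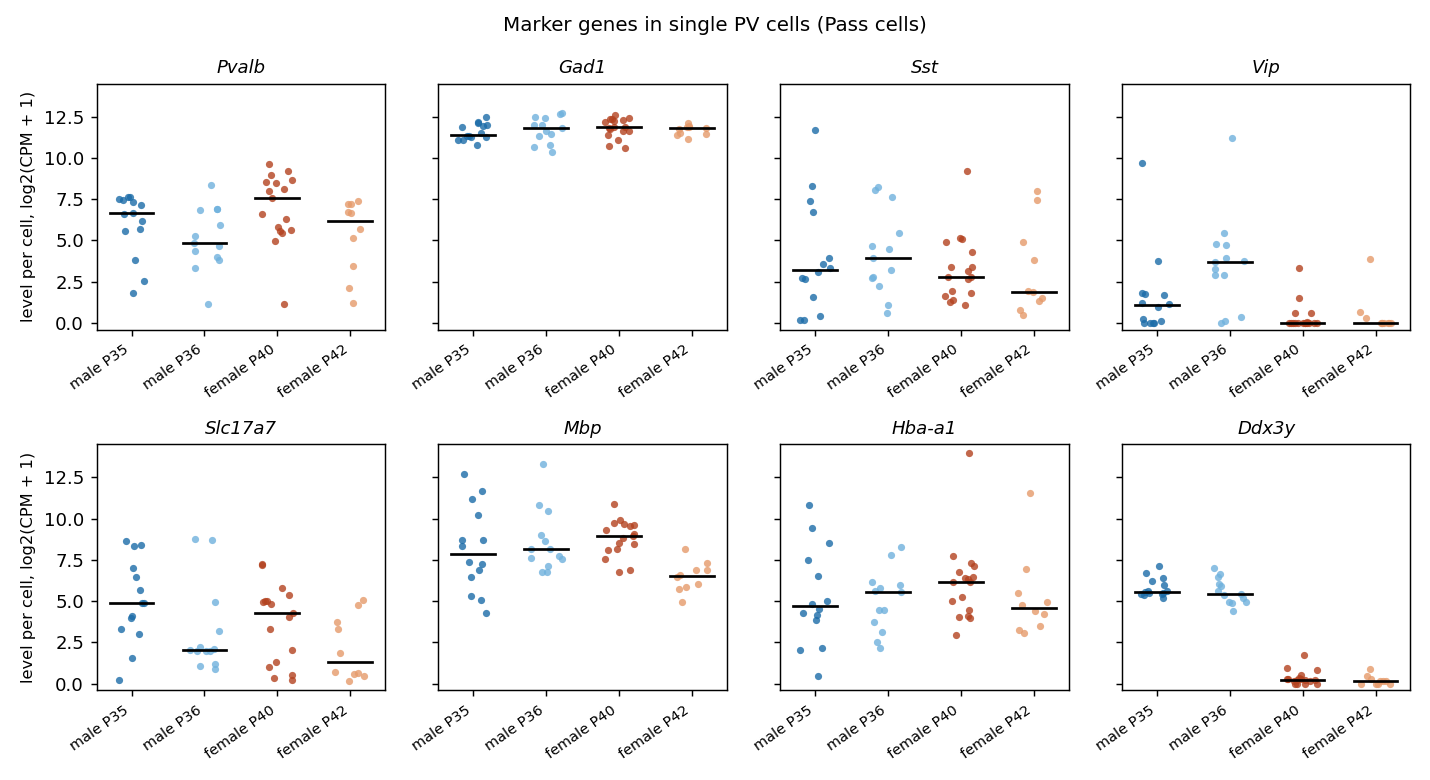
Levels of 8 marker genes in each Pass cell, as log2(CPM + 1) on the vertical axis, by sex and age pool on the horizontal axis; each point is 1 cell and each black bar the pool's median over cells. Ddx3y reached 1 CPM in 27 of 27 male and 1 of 27 female cells, and Vip in 17 male and 3 female cells.

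The main comparison asked which genes differed between female and male PV cells. Only Y-linked genes passed the test: Ddx3y, an RNA helicase, and Eif2s3y, a translation initiation factor subunit, were higher in the male pools. Ddx3y was at 51.0 and 53.0 CPM in the male pools and at 0.312 and 0.138 CPM in the female pools, scaled by the trimmed mean of M-values (TMM) as are all pool levels here, a log2 difference (female minus male) of -7.82 (standard error 0.64). Eif2s3y was at 36.5 and 35.8 CPM against 0.160 and 0.187 CPM (-7.70, standard error 0.64). Both had an adjusted p of 0.0205 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the only 2 calls among 14933 genes. The Y-linked histone demethylases Kdm5d (-7.67, standard error 1.01, edgeR adjusted p = 0.162) and Uty (-7.25, standard error 1.15, edgeR adjusted p = 0.357) had differences of similar size without passing in this fit. DESeq2 called both (adjusted p = 1.4e-18 and 4.4e-13), as did edgeR with no filter on low counts (1.3e-06 and 0.00039). Summed over these 4 genes, the male Pass cells held 48.1 to 307 CPM and the female Pass cells 0 to 3.84 CPM, with at least 1 count in 25 of 27 female cells. Xist, the X-inactivation RNA, was not analysed here.

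At an unadjusted p under 0.05 edgeR gave 823 genes, 5.51% of those tested, 396 higher in the female and 427 higher in the male pools. The pools of one sex lay wholly above those of the other for 5056 genes, or 33.9%, where 33.3% are given by chance with 2 pools against 2. DESeq2 on the same sums called 186 genes and limma on mean log2(CPM + 1) called 2. The DESeq2 calls included Ddx3y, Eif2s3y, Kdm5d, Uty, Vip, Galnt14, Hba-a1, Hbb-bs and Alas2. Without the male P35 pool edgeR called 1 gene (Vip) and without the male P36 pool 0, and the adjusted p of Ddx3y and Eif2s3y then lay between 0.469 and 0.653, while their log2 differences kept their size (Ddx3y -7.86 and -7.80, Eif2s3y -7.68 and -7.71). Without 7 cells of high Vip, globin, microglial or oligodendrocyte marker levels, an alternative chosen after seeing the data, Ddx3y alone was called and the adjusted p of Eif2s3y was 0.0883 in edgeR, with a log2 difference of -7.48 (adjusted p from 4.3e-49 to 0.653 for these 2 genes over all alternatives).

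Small p-values also belonged to other genes, several of them of other cell types, none of which passed the adjusted test in the main edgeR fit. Without female P40, with 1 female pool left, the log2 differences of Hba-a1, Vip, Alas2 and Galnt14 were 2.46, -8.11, 4.59 and -6.97. That of Hba-a1 was 3.09 without female P42. Vip was called in edgeR on cells thinned to an equal total (adjusted p = 0.0346). Vip, a neuropeptide of another interneuron class, was at 45.3 and 351 CPM in the male pools and 0.710 and 0.708 CPM in the female pools (log2 difference -8.13, standard error 1.01, edgeR adjusted p = 0.153), and male cells 11 and 21 held 97.7% of the male Vip counts. Galnt14, a glycosyltransferase, was at 11.99 and 27.16 CPM against 0.108 and 0.155 CPM (-7.22, standard error 0.97), with 64.6% of its male counts in male cells 11 and 20. In the other direction, the globin gene Hba-a1 was at 102 and 54.8 CPM in the male and 665 and 432 CPM in the female pools (2.80, standard error 0.34, edgeR adjusted p = 0.153). Hbb-bs (2.83, standard error 0.50) and Alas2, the haem synthesis enzyme of red blood cells (4.44, standard error 0.59), went the same way. Female cells 16 and 27 held 90.4% of the female Hba-a1 counts, 90.8% of those of Hbb-bs and 93.8% of those of Alas2. Vcam1, an adhesion molecule, and Ptprc, the leukocyte antigen CD45, were at 5.79 and 13.04 CPM and at 10.3 and 4.36 CPM in the female pools and under 0.1 CPM in the male pools, with 85.1% and 77.1% of the female counts in 2 cells each. Ttll9, a tubulin-modifying enzyme, had 2 counts in the male pools and 1848 in the female pools, a ratio of CPM of 881 (exact 95% interval 244 to 7283, counting error only). Its log2 difference was 9.83 (standard error 1.86, edgeR adjusted p = 0.693). It reached 1 CPM in 6 female cells, and 2 cells held 49.2% of the female counts.

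**Figure D2:**
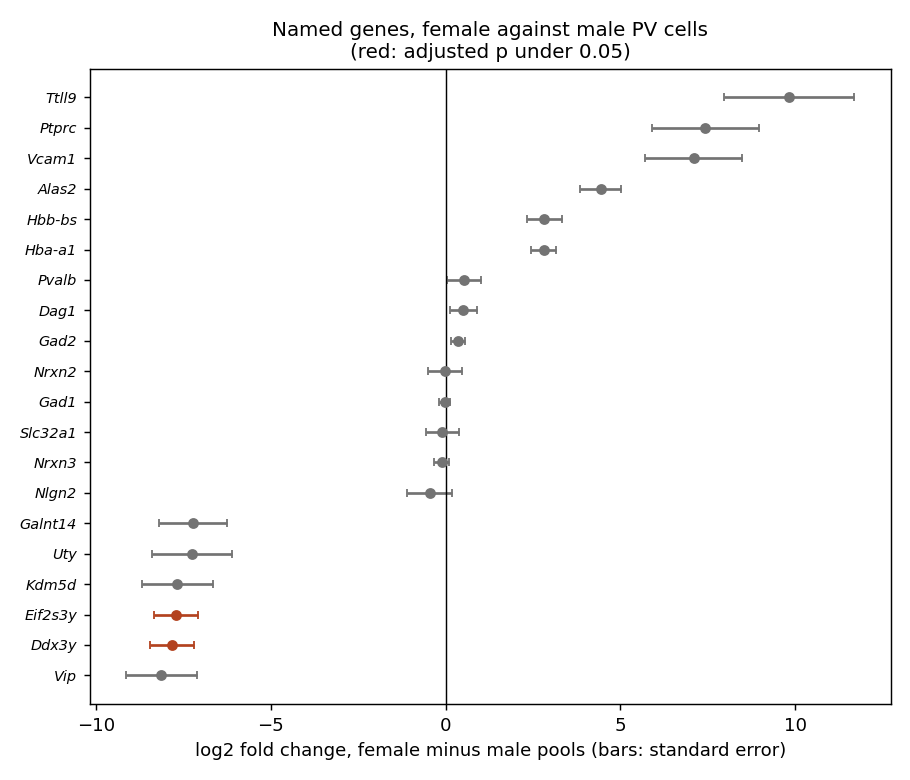
Log2 fold change of the named genes, female minus male pools (horizontal axis), with standard errors from edgeR as bars and 2 pools per sex; genes with an adjusted p under 0.05 are red. Ddx3y (-7.82) and Eif2s3y (-7.70) are red, and Nrxn2 and Nrxn3 lie at -0.02 and -0.11.

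In GRCm38 with the GENCODE vM21 annotation, the 2 called genes lie on chromosome Y. Ddx3y is at 1260771 to 1286629 on the minus strand and Eif2s3y at 1010543 to 1028847 on the plus strand. Counts are given per gene, and which parts of a gene were counted is not given in the sources used here. Vip lies on chromosome 10 (5639218 to 5647617), Hba-a1 on chromosome 11 (32283511 to 32284465) and Hbb-bs on chromosome 7 (103826534 to 103828096). Hba-a1 with Hba-a2, and Hbb-bs with Hbb-bt, are near-identical copies, so the split of reads within each pair is uncertain.

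Neurexins are presynaptic adhesion proteins that bind partners across the synaptic cleft, and Nrxn3 is the gene in the study's title. Nrxn3 was abundant in these cells and Nrxn2 was lower: the medians over 54 cells were 193 and 10.2 CPM. Nrxn3 lay above Nrxn2 in 54 of 54 cells (exact 95% interval 93.4% to 100%). CPM is not corrected for gene length, which limits such comparisons between genes. Between the sexes, Nrxn3 was at 217 and 162 CPM in the male and 184 and 167 CPM in the female pools, a log2 difference of -0.11 (standard error 0.21, edgeR adjusted p = 0.996). Nrxn2 was at 20.2 and 17.8 against 14.3 and 23.1 CPM (-0.02, standard error 0.49). Both differences were smaller than their standard errors and changed sign with some settings. The genes lie on chromosome 12 (Nrxn3, 88722876 to 90334935) and chromosome 19 (Nrxn2, 6418731 to 6544169).

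**Figure D3:**
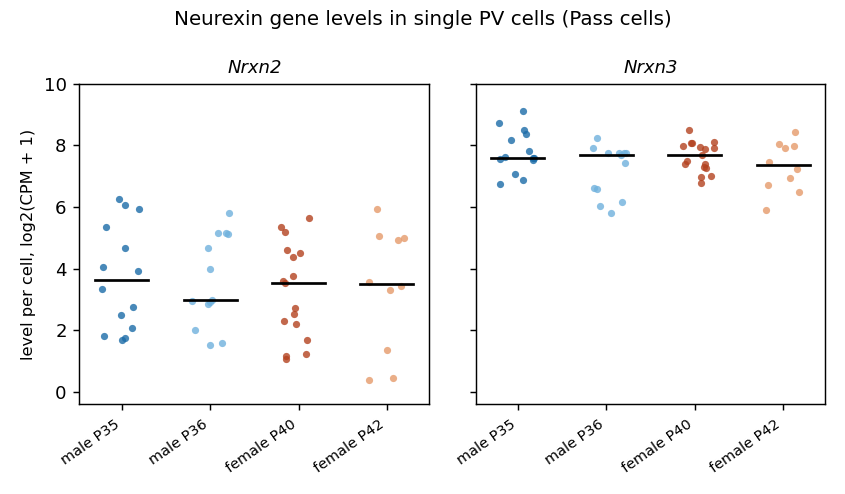
Levels of Nrxn2 and Nrxn3 in each Pass cell, as log2(CPM + 1) on the vertical axis, by sex and age pool; each point is 1 cell and each black bar the pool's median over cells. Nrxn3 lies above Nrxn2 in 54 of 54 cells.

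Neurexin transcripts differ by alternative splice sites (ss), which change which partners the protein can bind, and by promoter, which gives long alpha and shorter beta forms. In these PV cells Nrxn3 was almost always spliced with the ss4 insert: its share was 98.1% and 98.5% in the male and 97.1% and 99.7% in the female pools, a difference of 0.0693 points (exact permutation test, two-sided p = 1). Nrxn2 was mixed at ss4, with 96.8% and 59.4% in the male and 72.8% and 28.3% in the female pools, -27.5 points (exact permutation p = 0.667), a difference that went from -5.27 points without female P42 to -49.8 without female P40 and was -6.70 as the mean over cells. For Nrxn3 the included share at ss5 was 60.8% and 66.1% in the male and 48.2% and 53.0% in the female pools, -12.8 points, and at ss3 79.2% and 92.8% against 99.2% and 93.5%, 10.3 points, which became 3.54 points without male P35. The alpha share of Nrxn3 was 88.3% and 82.8% in the male and 79.9% and 47.2% in the female pools, -22.0 points, which became -5.67 points without female P42. At ss1 Nrxn3 had 95.6% and 93.8% against 98.5% and 98.5%, 3.81 points, and Nrxn2 at ss5 had 1.49% and 1.82% against 5.63% and 1.88%, 2.10 points, which became 0.226 points without female P40. Nrxn3 ss3 differed more without male P36, the Nrxn3 alpha share more without female P40, and Nrxn2 ss5 more without female P42. For these 5 features (Nrxn3 ss5, ss3, alpha share and ss1, and Nrxn2 ss5) the male and female pools did not overlap, and each had the smallest p that 2 pools against 2 can give, 0.333 in the exact two-sided permutation test, so none can be called. With the mean over cells in place of sums the pools overlapped for 3 of them, Nrxn3 ss5, Nrxn3 ss3 and Nrxn2 ss5, whose differences were then -7.92, 6.78 and 0.415 points. Of the 10 features compared, Nrxn3 ss2 was listed at 0% included in all 4 pools, and the other 4 overlapped between the sexes. Within pools the cells spread widely, with an SD over cells of 21.2 to 33.1 points for Nrxn3 ss5. The depth behind these values is unknown, since their unit is not given in the sources used here.

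**Figure D4:**
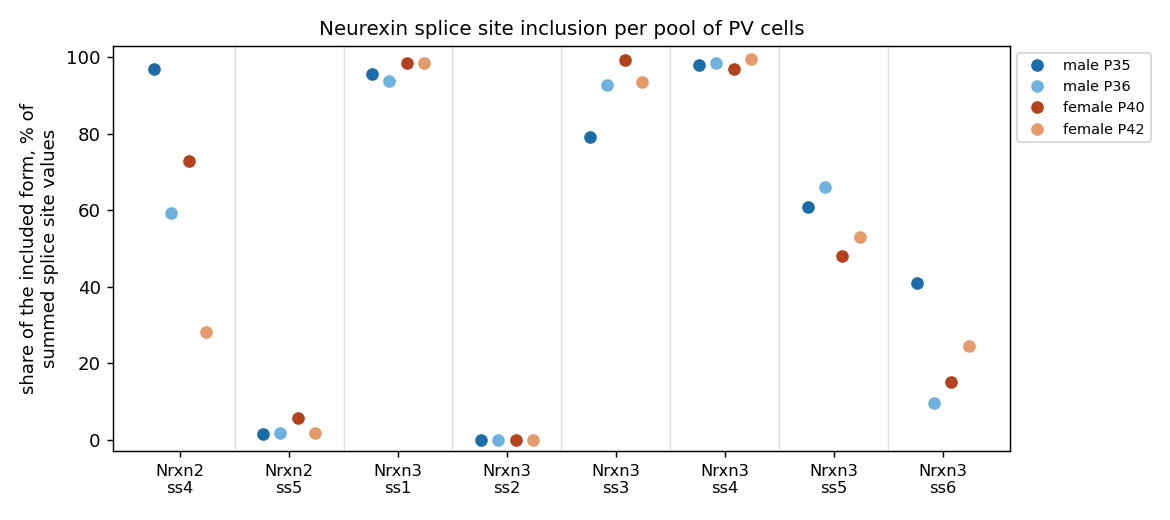
Share of the included form at each neurexin splice site compared, as a percentage of the summed splice site values (vertical axis); each point is 1 pool of cells, coloured by sex and age. Nrxn3 ss4 lies between 97.1% and 99.7% in all 4 pools, and Nrxn3 ss5 is at 60.8% and 66.1% in the male and 48.2% and 53.0% in the female pools.

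Gene lists fixed before the data were examined were compared as groups, to see whether sets with a shared role moved together even where single genes did not pass. With camera's preset correlation 10 of 27 lists passed an adjusted p of 0.05; with a correlation estimated from the 4 pools 0 did, and fry, which asks whether a list moves one way without comparing it with other genes, called 1, the sex chromosome list. Neurexin partners were lower in the female pools, 16 of 25 with a negative difference (median -0.29, camera adjusted p = 0.0342, adjusted p = 0.668 with an estimated correlation). Among them Lrrtm1, a postsynaptic neurexin partner, was at 61.1 and 67.4 CPM in the male and 15.2 and 22.7 CPM in the female pools (-1.76, standard error 0.35). It was the 1 member passing when adjusted over the list alone, against 0 over all genes in the main fit. DESeq2 called it over all genes (adjusted p = 0.00068), as did edgeR with no filter on low counts (0.0026). These 2 settings called 186 and 111 genes in all. RLE normalization, both limma inputs and detection in at least 20 cells called only Ddx3y and Eif2s3y. Nlgn2, the neuroligin of inhibitory synapses (-0.46, standard error 0.65), and Dag1, dystroglycan (0.51, standard error 0.37), did not pass. Calcium channel subunits were also lower in the female pools, 12 of 15 with a negative difference (median -0.20, camera adjusted p = 0.0295, adjusted p = 0.560 with an estimated correlation). There Cacna1e, the R-type channel, was at 22.3 and 32.6 CPM in the male and 3.14 and 4.996 CPM in the female pools (-2.76, standard error 0.59), 1 member adjusted over the list alone and 0 over all genes, and male cells 29 and 15, with the highest Slc17a7 levels of all Pass cells (428 and 409 CPM), held 53.4% of its male counts. Sex chromosome genes were lower (camera adjusted p = 4.5e-18, adjusted p = 0.227 with an estimated correlation), with 4 members adjusted over the list alone, the 4 Y-linked genes, and 2 over all genes. Its 4 X-linked members had positive differences that did not pass, such as Ddx3x (0.28, standard error 0.22). Mitochondrially encoded transcripts were higher in 13 of 13 members (median 0.76, camera adjusted p = 1.6e-05, adjusted p = 0.708 with an estimated correlation), among them mt-Nd1 (0.76, standard error 0.34). Female P40 held the highest levels of these transcripts, at 6995 CPM of mt-Nd1 against 3480, 3857 and 2318 CPM in female P42, male P35 and male P36, and 0 members passed over all genes or over the list alone. Female cells 3 and 27, both of female P40, held 41.98% of the female mt-Nd1 counts. Mitochondrial transcripts made up 4.46% and 10.87% of their counts. Medians over cells were 1.80% in male P35, 0.824% in male P36, 1.89% in female P40 and 1.23% in female P42. Without female cell 3 the mitochondrial list still passed (median 0.52, camera adjusted p = 0.000302). It also passed without the 7 cells of high marker levels, female cell 27 among them (median 0.66, camera adjusted p = 0.000953). These lists moved beside markers of other cell types, such as those of excitatory neurons (median -1.53), and without the 7 cells of high marker levels the neurexin partner and calcium channel lists no longer passed (camera adjusted p = 0.0685 for both), while their medians were -0.24 and -0.29, against -0.29 and -0.20 in the main fit. The neurexin partner list also did not pass without male P35 (median 0.085, camera adjusted p = 0.635), without female P40 (median -0.24, camera adjusted p = 0.408) or on cells thinned to an equal total (median -0.19, 0.0652). The calcium channel list did not pass without male P35 (median 0.019, camera adjusted p = 0.368) or without female P42 (median -0.20, 0.0612), and its median was -0.60 on thinned cells. The mitochondrial list did not pass without female P40 (median 0.013, camera adjusted p = 0.761) or without male P36 (median 0.41, 0.133), and its median was 0.39 on thinned cells.

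Markers of other cell types also differed as groups, and 6 of the 9 cell type lists passed with the preset correlation. Markers of other interneurons were lower in the female pools, 11 of 13 with a negative difference (median -1.75, camera adjusted p = 3.8e-09, adjusted p = 0.227 with an estimated correlation). Vip and Sst, at 249 and 96.5 CPM in the male and 42.2 and 48.9 CPM in the female pools (-1.92, standard error 0.42), passed when adjusted over the list alone, and 0 over all genes. Male cell 5 held 56.1% of the male Sst counts, and without it, a fit added after seeing the data, the difference was -0.82 (standard error 0.30). Cck had a difference of -1.01 (standard error 0.33). Excitatory neuron markers were lower in 8 of 10 members (median -1.53, camera adjusted p = 1.5e-06, adjusted p = 0.542 with an estimated correlation). Male cell 29 held 66.9% of the male counts of Slc17a6, and male cells 29 and 20 held 47.4% of those of Slc17a7. Slc17a7 reached 10 CPM in 13 of 27 cells of each sex, with medians of 8.83 CPM in male and 9.11 CPM in female cells. The glutamate transporters Slc17a7 (-2.61, standard error 0.56) and Slc17a6 (-4.41, standard error 1.26) passed when adjusted over the list alone, and 0 members over all genes. Without female P40, the female pool with the higher levels of both, 1 female pool is left, and the differences were -3.73 and -7.16. Oligodendrocyte markers were lower in 8 of 8 members (median -2.33, camera adjusted p = 3.4e-12, adjusted p = 0.542 with an estimated correlation). Adjusted over the list alone 1 member passed, with 0 over all genes, and Mbp (-1.12, standard error 0.62) and Mog (-3.97, standard error 1.43) did not pass. Mbp was at 574 CPM in female P40 and 112 CPM in female P42, and without female P40, with 1 female pool left, its difference was -2.73. Male cells 19 and 27 held 87.5% of the male Mog counts. With the preset correlation these 3 lists also passed without each pool, on thinned cells and without the 7 cells, but without the 7 cells the medians of the other interneuron and oligodendrocyte lists were -0.90 and -0.89. The other interneuron and excitatory medians were -1.08 and -0.998 without male P35, and the oligodendrocyte median was -1.44 without female P42 and -3.69 without female P40.

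Blood, microglial and astrocyte markers went the other way. Blood genes were higher in the female pools in 5 of 5 members (median 2.80, camera adjusted p = 1.8e-27, adjusted p = 0.227 with an estimated correlation), 5 adjusted over the list alone and 0 over all genes. Microglial markers were higher in 10 of 10 members (median 1.06, camera adjusted p = 0.000529, adjusted p = 0.708 with an estimated correlation), such as Ctss (1.40, standard error 0.43) and C1qb (1.05, standard error 0.62), with 0 adjusted over the list alone. Astrocyte markers were higher in 8 of 9 members (median 0.39, camera adjusted p = 0.0288, adjusted p = 0.722 with an estimated correlation), such as Mfge8 (1.41, standard error 0.41) and Gja1 (1.47, standard error 0.57), with 0 adjusted over the list alone. Without the 7 cells the blood and astrocyte lists no longer passed (camera adjusted p = 0.743 and 0.695), and the microglial list turned to a median of -0.40 (camera adjusted p = 0.0444). The cells chosen for globin or microglial levels were female only, so a fall of a female excess was built in. Male cell 24 (1800 CPM of Hba-a1) and male cells 1 and 28 (730 and 577 CPM of C1qb) stayed in. Without female P40 the microglial and astrocyte lists turned to medians of -0.48 and -0.051 (camera adjusted p = 0.386 and 0.910). The difference of Ctss was then 0.55 and that of C1qb -0.57, and female cell 21 alone held 57.6%, 58.2% and 62.8% of the female counts of Ctss, C1qb and Gja1. The microglial list also did not pass on thinned cells (median 0.49, camera adjusted p = 0.571), nor the astrocyte list without male P36 (median 0.34, camera adjusted p = 0.320).

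The other 17 lists did not pass camera's test in the main fit. They covered neurexins, sex steroid receptors, GABA synthesis and transport, the inhibitory postsynapse, glutamate receptors, sodium and potassium channels, other synaptic adhesion genes, nuclear genes of oxidative phosphorylation and ribosomal proteins, each with a camera adjusted p of 0.987. The remainder were stress and heat shock genes (0.981), GABA receptors (0.690), neuronal splicing regulators (0.491), oligodendrocyte precursors (0.416), activity-dependent early genes (0.232), endothelial and mural cells (0.217), PV interneurons (0.217) and the release machinery (0.153). Over all genes 0 members of these lists passed edgeR's test, and adjusted over the list alone 1 did, the endothelial gene Ly6c1, at 0.763 and 13.4 CPM in the male and 0.0216 and 0.0407 CPM in the female pools (log2 difference -7.82, standard error 1.995). Male cell 16 held 88.8% of its male counts, and without that cell, a fit added after seeing the data, the difference was -4.72 (standard error 1.84). The direction of camera's test and the sign of the median differed for the inhibitory postsynapse, oxidative phosphorylation, other adhesion and stress lists, whose medians lay between -0.02 and 0.02. Among GABAergic genes Gad2 was at 339.7 and 293 CPM in the male and 349.9 and 464 CPM in the female pools (0.36, standard error 0.20). Pvalb was at 104 and 82.5 against 206 and 62.0 CPM (0.52, standard error 0.48), and turned to -0.58 without female P40. Gad1 (-0.03, standard error 0.17) and Slc32a1 (-0.09, standard error 0.46) differed by less than their standard errors, with a sign that changed under several settings.

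Membrane values recorded from the same cells were compared between the sexes as the labels give them, without units. The resting value (vrest) averaged -60.5 ± 5.59 (SD over cells, n = 14) in male P35, -58.8 ± 5.99 (n = 13) in male P36, -58.9 ± 4.79 (n = 15) in female P40 and -56.3 ± 2.43 (n = 7) in female P42. The female minus male difference of pool means was 2.05 (exact permutation test of 2 pools against 2, two-sided p = 0.667), and went from 0.758 without female P42 to 3.34 without female P40. For rm the pool means were 328 ± 146 (n = 12), 282 ± 156 (n = 13), 314 ± 161 (n = 15) and 331 ± 201 (n = 9) in the same order, a difference of 17.5 (exact permutation p = 0.667). For cm they were 44.5 ± 18.4 (n = 12), 51.6 ± 24.9 (n = 13), 38.1 ± 13.1 (n = 15) and 42.6 ± 19.4 (n = 9), a difference of -7.75, lower in both female pools (exact permutation p = 0.333, the smallest this design allows), which became -4.19 without male P36. With medians in place of means the rm difference was -23.0. The vrest medians were -61.8 and -60.0 in the male and -59.0 and -55.0 in the female pools, which did not overlap, unlike the means.

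The 4 Fail cells were set beside the Pass cells, since the criterion behind the label is not given in the sources used here. Male cells 3 and 4 and female cell 6 had 0.836, 0.596 and 0.545 M counts, below every Pass cell. Female cell 10 had 5.08 M, more than 8 of the 54 Pass cells, but 10871 genes detected, below the Pass range of 11591 to 14351. Its Pvalb level, 1030 CPM, was above that of every Pass cell, and its Nrxn2 level, 0.197 CPM, was below that of every Pass cell. Female cell 6 detected 10784 genes, also below the Pass range, and male cells 3 and 4 detected 12261 and 12838. Gad1 in the 4 cells, 2111 to 5958 CPM, lay within the Pass range of 1337 to 6751 CPM.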

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

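Of the tests below, that of reads carried over from male cell 11 was chosen only after the result was seen; for the tests that leave out named cells the levels per cell had been seen first, and the fits without all 7 cells were seen before the fits without each pair.

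Among 21 values tested in groups of 4 to 10 cells, 2 stood apart from the rest of their group, and chance alone flags about 1 in 20 groups. Among the 4 Fail cells the total of female cell 10, 5.08 M counts, was far above the next, 0.836 M, a gap of 0.936 of the group's range. Among the 10 Pass cells of female P42, Slc32a1 in female cell 15 was 63.7 CPM against 32.2 CPM in the next cell, a gap of 0.538 of the range.

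Vip was higher in both male pools, and male cells 11 (2329 CPM) and 21 (809 CPM) held 97.7% of the male counts. Without these 2 cells the log2 difference, female minus male, went from -8.13 (standard error 1.01) to -2.91 (standard error 1.52), which neither removes it nor leaves it beyond the limit set for the test, so whether the 2 cells account for all of it cannot be told apart. Of the other 12 cells of male P36, male cells 25, 26 and 29 held 0.0918, 0 and 0.310 CPM, and the highest held 42.1 CPM. The 12 cells held a mean of 12.97 CPM, 0.557% of the level in cell 11, while 3 of 27 female cells reached 1 CPM. Reads carried over from cell 11 are a candidate explanation of that low level, but the test cannot decide it. Egfr and Fbln1, the 2 other genes high in cell 11 and rare outside the pool, were examined in the same 12 cells. They were at 0.673% and 1.21% of their level in cell 11, so 100% of them reached the level the test asked for. Their means there were 0.345 and 0.837 CPM. The choice of genes allowed up to 1 CPM in at least 90% of the cells outside the pool. Background at that level could pass the test without carried-over reads. Also, 2 genes are too few to decide, and a first criterion that named 1 gene, Galnt14, was set aside. In male P35, male cells 17 to 24 other than cell 21 held 0.977 to 12.6 CPM, while male cells 1, 2, 5, 6, 7 and 8 held 0 to 0.199 CPM. The test of carried-over reads did not cover the cells of male P35. Sex and age, which the design names, remain open and untested as reasons for a difference in Vip.

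Globin genes were higher in both female pools, and female cells 16 and 27 held 90.4% of the female Hba-a1 counts. Without them the log2 difference of Hba-a1 went from 2.80 (standard error 0.34) to -0.54 (standard error 0.43), and that of Alas2 from 4.44 (standard error 0.59) to 0.94 (standard error 1.48), but to 3.08 (standard error 1.84) without all 7 cells, so whether Alas2 follows Hba-a1 is left open. The 2 cells were chosen for holding these counts and on the female side only, so a fall was built into the fit. Male cell 24, at 1800 CPM of Hba-a1, stayed in. A candidate explanation is blood RNA taken up with female cells 16 and 27, which held 2988 and 15907 CPM of Hba-a1. A difference between the animals of each sex or age was not tested.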

How the results depend on the processing

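The fits without 7 cells of high marker levels, without female cell 3 and without male cell 5 (Sst) or 16 (Ly6c1) were chosen after seeing the data, and the other alternatives were listed beforehand. The pools give 2 values per sex, and the number of calls differed between settings, for reasons that were not tested. With RLE normalization, with detection in at least 20 cells, with Fail cells added or without female cell 3, edgeR called 2 genes each. Both limma inputs gave 2 calls, and edgeR on thinned cells gave 3, with Vip the added one. DESeq2 called 186 genes (70 higher in the female and 116 in the male pools), and edgeR with no filter on low counts called 111 (58 and 53). Ddx3y and Eif2s3y kept their direction under every alternative; their calls were lost without either male pool, and that of Eif2s3y without the 7 cells. Of the 99 named genes reported here 66 never changed sign, and of 1383 values 78 had the other sign; 58 values of genes not called by edgeR passed under another setting. Of the 9 splice features other than Nrxn3 ss2, which was 0% throughout, 6 never changed sign, nor did 2 of 3 membrane values. Nrxn3 ss5 lay between -7.92 and -15.5 points under all alternatives. Each fit without 1 pool leaves 1 pool on its side, which is assumed to vary like the others. No paired analysis was possible because the replicate numbers only name cells. Depth limits low genes: thinned to 2054581 counts per cell, Pdgfra had a count in 48.1% of male and 29.6% of female cells (77.8% and 55.6% before), Pecam1 in 22.2% of female cells (40.7% before) and Mag in 37.0% of male cells (81.5% before). The cause of the changes listed next was not tested.

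Log2 differences (female minus male) that changed sign were as follows. Without the 7 cells, where edgeR called 1 gene (higher in the male pools), they were Ctss -0.19, Csf1r -0.29, C1qb -0.47, Rgs5 0.34, Kcnab3 0.017, Slc32a1 0.19 and Slc1a2 -0.28. With limma on mean log2(CPM + 1) they were Pdgfra -0.43, Olig1 -0.86, Aldh5a1 0.32, Cadm1 0.085, Itm2a -0.55, Hspa8 0.094, Kcnab3 0.22, Slc32a1 0.032, Gad1 0.10 and Slc1a2 -0.45. With limma on the authors' normalized signal they were Pdgfra -0.95, Atp5b 0.0022, Clstn1 0.023, Olig1 -1.11, Aldh5a1 0.41, Cadm1 0.14, Itm2a -1.10, Nrxn3 0.028, Gria2 0.045, Hspa8 0.15, Snap25 0.042, Kcnab3 0.28, Slc32a1 0.098, Gad1 0.15 and Slc1a2 -0.51. On thinned cells they were Olig1 -0.025, Itm2a -0.075, Gria2 0.027, Hspa8 0.076, Kcnab3 0.080 and Gad1 0.034. Without female cell 3 they were Olig1 -0.36, Itm2a -0.61, Gad1 0.035 and Nrxn2 7.8e-05.

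Leaving out each pool in turn, edgeR called 0 to 26 genes, 0 to 11 higher in the female and 0 to 15 higher in the male pools. Of the neurexins and GABAergic genes, the log2 differences ranged for Nrxn2 from -0.39 to 0.29, Nrxn3 from -0.31 to 0.12, Pvalb from -0.58 to 1.15, Gad1 from -0.19 to 0.15, Slc32a1 from -0.53 to 0.55 and Aldh5a1 from -0.74 to 0.31. Of other synaptic and channel genes they ranged for Nlgn2 from -0.99 to 0.39, Clstn1 from -0.59 to 0.10, Ptprs from -0.31 to 0.042, Iqsec3 from -0.16 to 0.88, Slc12a5 from -0.17 to 0.32, Kcnc2 from -0.0054 to 0.22, Kcnab3 from -0.057 to 0.012, Snap25 from -0.12 to 0.049 and Elavl4 from -0.032 to 0.10. Of markers of other cells they ranged for Olig1 from -0.060 to 1.84, Rgs5 from -7.37 to 1.56, Itm2a from -1.68 to 1.69, Csf1r from -0.46 to 2.11, C1qb from -0.57 to 1.80, Aldoc from -0.051 to 0.45 and Slc1a2 from -0.91 to 0.93. Of the rest they ranged for mt-Cytb from -0.036 to 1.16, mt-Co1 from -0.093 to 1.11, Rpl4 from -0.29 to 0.075, Eif2s3x from -0.25 to 0.66, Dusp1 from -0.14 to 0.66 and Hspa8 from -0.26 to 0.13.

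Of 27 gene lists camera called 10, and 0 with an estimated correlation; fry called 1 and camera without the 7 cells 6, where the median of the microglial list was -0.40. Without 1 pool that median ranged from -0.48 to 1.76 and that of astrocyte markers from -0.051 to 0.93. Lists not called in the main fit moved too. The median of early genes ranged from -0.13 to 0.53 and that of oligodendrocyte precursors from -0.28 to 1.84. That of endothelial and mural genes ranged from -5.995 to 0.12. The splice differences without 1 pool ranged, in points, for Nrxn2 Alpha from -3.02 to 3.85, Nrxn3 ss4 from -1.24 to 1.37 and Nrxn3 ss6 from -21.3 to 10.1. The difference of rm ranged from -5.44 to 40.4 without 1 pool and was -23.0 with the median per pool.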

Other observations

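No tests of explanations were run for the values here; the genes come from the rule for named genes, but were picked for this part after their values were seen.

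Several abundant neuronal genes differed between the sexes by less than their standard errors. The synaptic genes Snap25, a vesicle fusion protein (5580, 5649, 5123 and 5779 CPM in male P35, male P36, female P40 and female P42), and Cplx1, complexin (2295, 2561, 2451 and 2692 CPM), had log2 differences of -0.04 (standard error 0.14) and 0.08 (standard error 0.15). The potassium channel subunits Kcnc2 (577, 496, 530.2 and 624 CPM) and Kcnab3 (402, 394, 398 and 381 CPM) had differences of 0.10 (standard error 0.17) and -0.03 (standard error 0.16). The neuropeptide gene Tac1, listed among PV markers, was at 814 and 543 CPM in the male and 880.3 and 1292 CPM in the female pools (0.68, standard error 0.25, edgeR adjusted p = 0.887). Atf3, a stress-induced transcription factor, was at 16.2 and 15.5 CPM in the male and 113 and 30.2 CPM in the female pools. Its difference was 2.18 (standard error 0.58, edgeR adjusted p = 0.878 in the main fit), and female cell 21 held 66.7% of its female counts. Whether Atf3 was called depended on the setting.

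Splits of the 4 pools that mix the sexes called 0 genes each in edgeR, with 750 and 620 genes at an unadjusted p under 0.05, against 2 called and 823 for the real split. With 3 splits in all no share under 0.05 can be had, so these counts only describe the pools.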
